A study of Mus musculus with 60 samples.

How the data were processed

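The series covers 60 ChIP-seq samples of mouse tissues and cells, of which 31 had a peak list and were used. These were 15 CTCF lists, 15 Pol2 lists and 1 p300 list, all of strain C57BL/6 where the labels give one. The other 29 samples, among them 22 input controls, were not analysed here, so no background from input was available to set beside the peaks. Groups were taken from the sample titles (target, tissue and age), with 1 sample in each. Every sample had 2 read files, and whether these were pooled before peaks were called is not given in the sources used here. With 1 list per group, p-values measure the spread between tissues, which includes technical differences between libraries.

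Per the labels, the CTCF and p300 antibodies were rabbit polyclonal and the Pol2 antibody was a mouse monoclonal. Per the series' design text, fragments were read for 36 cycles on Illumina instruments and aligned to the mouse genome mm9 with ELAND or Bowtie, with a seed length of 25 and up to 2 mismatches. Reads that mapped to 1 place were kept, and reads with the same start and strand were discarded as clonal. The mm9 build also stands in the submitters' processing notes. The labels name ELAND for 7 CTCF and 8 Pol2 lists and Bowtie for 8 CTCF and 7 Pol2 lists, and this label was treated as a technical batch. For 7 tissues both lists carry the ELAND label and for 7 both carry the Bowtie label. Spleen has 1 of each. The peak caller and its threshold are not given in the sources used here.

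The deposited lists give a position and a score per peak, the authors' own value, whose scale is not stated. It was used only to rank or filter peaks within a list. Every deposited peak was 1000 bp wide, so list width carries no information, and the planned comparison of peak widths gave 0 by construction and was replaced by the share of peaks with another peak of the list starting within 2 kb. The liver Pol2 list held 1881 peaks with a score below 1 (lowest -0.093), while all other lists began at 1 or above. Lists gave no p-values, counts or depths, so the number of reads behind a peak is unknown, and a short list can reflect shallow reads, a strict threshold or few sites.

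The reference genome supplied, NCBIM37, has the chromosome lengths of mm9, and the GENCODE M1 annotation of that build was used. All listed peaks lay on the 21 assembled chromosomes considered (1 to 19, X and Y). Peaks were called overlapping when they shared at least 1 bp. Overlapping or touching peaks of the 15 lists of a target were joined into regions. A promoter was the window within 1 kb of any transcription start of 22367 protein-coding genes. For genes named with a region, the order was a gene with a start within 1 kb, then an overlapping gene, then the nearest protein-coding gene.

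Before the data were examined, 26 gene lists of 8 to 12 genes were fixed. There were 15 tissue marker lists, and neuronal, leukocyte, housekeeping, ribosomal, cell cycle, immediate early, erythroid, endothelial, fibroblast, adipose and skeletal muscle lists. All 281 entries were found in the annotation, 2 of them under older symbols (Mtap2 for Map2, Sfpi1 for Spi1). Neural tissues were cortex, cerebellum, olfactory bulb and E14.5 brain, and blood tissues were bone marrow, spleen, thymus and macrophages. Genes were named by a rule fixed at the same time. From each tissue list it took the 2 genes with a promoter Pol2 peak in their own tissue and in the fewest other tissues, with ties decided by signal percentile. It added 1 gene without such a peak, the first in alphabetical order. It further took the 8 regions of highest mean signal percentile in each system-restricted or E14.5-restricted set, and fixed gene clusters. For liver no gene lacked a peak. Other genes named as members of a list, and the 6 tissues drawn for the Hoxd map, were chosen after their values were seen. The annotation lacks most single genes of the protocadherin alpha and gamma clusters, so the spans of Pcdha11 and Pcdhgc5, which cover the clusters, were used.

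Paired differences between CTCF and Pol2 over tissues were tested with the exact two-sided sign-flip permutation test. Classes of tissues were tested exactly over every choice of as many tissues, one-sided for similarity and restricted regions and two-sided for the gene lists of a class. Tissue marker lists and same-tissue overlap were tested with 100000 random assignments, one-sided. Benjamini-Hochberg adjustment covered the 17 planned tests, of which 8 had an adjusted p below 0.05, and separately the 6 tests of neuronal, leukocyte and cell cycle lists, which were added after seeing the data. Shares of p300 peaks carry exact Clopper-Pearson 95% intervals, which cover counting error only. Expected overlap was computed from the length covered by the peaks of a list and a genome of 2.65 Gb.

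Alternatives were an overlap of at least 500 bp, the upper 50% of each list by score, all lists of a target limited to the length of the shortest, autosomes only, regions joined within 1 kb, an overlap coefficient in place of the Jaccard index, a 5 kb promoter window, the whole gene body, each aligner batch alone, and each tissue left out in turn. Removal of liver Pol2 peaks below 1, removal of the 3 tissues with the shortest Pol2 lists, the clustering measure and the alternatives for the class gene lists were added after seeing the data. The CTCF core sequence CCASYAGRKGGC was searched on both strands with up to 1 mismatch, also added after seeing the data, with windows moved by 5 kb as the background.

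Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, and samtools 1.23.1 for the genome index. The overlap function was checked against bedtools 2.31.1 for heart CTCF and Pol2 and differed by 0 peaks. The procedures were tested on simulated data. For restricted regions, 100% of 200 planted neural regions were recovered among 40642 simulated regions, and 3.5% of 200 draws without such regions passed a p of 0.05. Simulated sites never overlapped and planted regions were set in exactly the neural lists, so the recovery was fixed in advance. It checks the counting only, since no shifted peaks, missed peaks or batches were simulated. For the tissue marker lists, 100% of 100 draws with a planted excess of 20 points and 4% of those without were called. For paired differences over 15 tissues, 95% of 100 draws with a shift of 1 SD and 4% of those without were called. For class similarity, 6% of 100 draws without a class were called.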

Results

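Peak lists from chromatin immunoprecipitation sequencing (ChIP-seq) were analysed for CTCF, a zinc-finger protein that binds insulators and chromatin loop anchors, and for RNA polymerase II (Pol2) in 15 mouse tissues or primary cells. A list for p300, a histone acetyltransferase that marks active enhancers and promoters, was analysed in heart. The tissues were cortex, cerebellum, olfactory bulb, heart, lung, liver, kidney, small intestine, testis, thymus, spleen, bone marrow and bone marrow-derived macrophages at 8 weeks of age, and whole brain and limb at embryonic day 14.5 (E14.5). Each combination of tissue and target had 1 list, so no tissue had a replicate. The tissue was the unit of every test (n = 15), and an SD is the spread between tissues. CTCF lists held 14512 (olfactory bulb) to 53124 peaks (thymus), and Pol2 lists held 5562 (spleen) to 29287 peaks (heart). The heart p300 list held 39447 peaks. Read depth was unknown, so a promoter without a listed peak was not shown to be free of Pol2. All positions are on mouse genome build mm9.

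The first comparison asked whether Pol2 occupied the genes characteristic of each tissue. A Pol2 peak lay within 1 kb of a transcription start for 72.9% ± 18.2 (SD, n = 15) of the genes in a tissue's own marker list. The same lists reached 16.0% ± 9.66 in the other 14 tissues. Of 168 tissue markers, 124 had such a peak in their own tissue, and 44 of these had one in no other tissue. The own tissue ranked highest alone for 12 of the 15 lists, tied for spleen, and was exceeded for cerebellum and olfactory bulb. After the mean of each tissue over all lists was subtracted, the own tissue lay 56.9 percentage points ± 18.9 above the others and was higher in 15 of 15 tissues. The one-sided permutation p was 1e-05, the smallest that 100000 assignments can give, and the adjusted p was 8.5e-05. The difference was 56.7 points in the ELAND lists and 55.1 points in the Bowtie lists, the 2 aligner labels treated as batches (adjusted permutation p = 0.00065 and 0.0048).

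**Figure D1:**
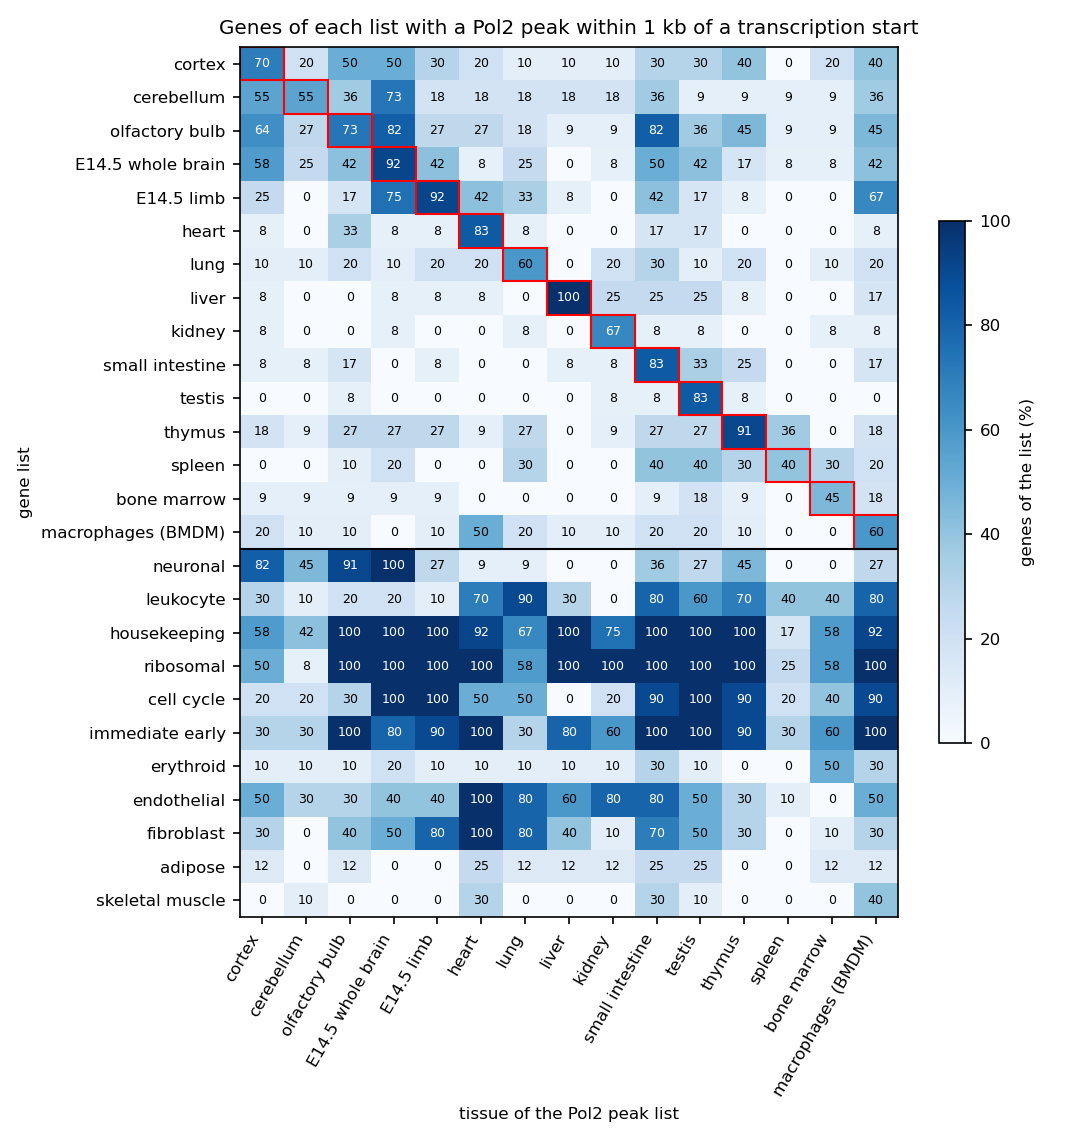
Percentage of the genes of each list (rows) with a Pol2 peak within 1 kb of a transcription start in each tissue's peak list (columns), from 0 to 100%. Red squares mark each tissue's own list, from 40% in spleen to 100% in liver, and the rows under the black line are the 11 further gene lists.

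In liver, all 12 listed genes had a promoter peak, against 9.52% ± 9.73 of them in the other 14 tissues. They included Alb, which encodes serum albumin (chromosome 5, 90889915 to 90905629, plus strand, peak at 90889513 to 90890512), and Tat, tyrosine aminotransferase (chromosome 8, peak at 112513896 to 112514895). Both genes had a promoter peak in liver alone, at the 97.9 and 99.7 signal percentiles of that list. In kidney, 8 of 12 genes were occupied, among them Cdh16, kidney cadherin, and Slc22a6, an organic anion transporter. Kap, a kidney androgen-regulated gene, had no promoter Pol2 peak in any of the 15 tissues. In small intestine, 10 of 12 were occupied, among them Alpi, intestinal alkaline phosphatase, and Lct, lactase, but not Cdh17. In lung, 6 of 10 were occupied, among them Sftpd, surfactant protein D, and Cldn18, a tight-junction claudin. The club-cell secretoglobin gene Scgb1a1 had no promoter peak in lung but had a Pol2 peak on the gene body. In testis, 10 of 12 were occupied, among them the protamine gene Prm1 (chromosome 16, peak at 10796362 to 10797361) and the germ-cell helicase gene Ddx4, and the 12 genes were occupied in 2.38% ± 3.91 of cases in the other 14 tissues. Pgk2, the spermatogenic phosphoglycerate kinase gene, had no peak.

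In heart, 10 of 12 cardiac genes were occupied, against 7.74% ± 9.51 in the other tissues. They included Myl2, the ventricular myosin light chain gene (chromosome 5, 122550960 to 122563481, plus strand, peak at 122550520 to 122551519, 98.6 percentile), and Myh6, the alpha-myosin heavy chain gene (chromosome 14, 55560758 to 55585764, minus strand, peak at 55584771 to 55585770), both in heart alone. Nppa, the atrial natriuretic peptide gene, had no promoter peak. In E14.5 limb, 11 of 12 patterning and mesenchymal genes were occupied, with Hoxd12 in limb alone and Hoxd13 in limb and E14.5 brain. Myog, the myogenin gene, had no Pol2 peak in limb. In E14.5 whole brain, 11 of 12 neural progenitor genes were occupied, including the proneural gene Neurog1 in that tissue alone and Lin28b, which encodes an RNA-binding protein, there and in cortex. Nhlh1 had no promoter peak but had a Pol2 peak on the gene.

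In the adult brain regions, marker genes were often occupied in other tissues as well. In cortex, 7 of 10 genes were occupied, including the transcription factor genes Tbr1 and Neurod6 in cortex alone. Arc, an activity-regulated gene, had a promoter peak in 12 other tissues and none in cortex. In cerebellum, 6 of 11 were occupied, including Gabra6, the granule-cell GABA-A receptor subunit gene, in cerebellum alone (chromosome 11, peak at 42132681 to 42133680, 99.7 percentile) and Pvalb, parvalbumin, in cerebellum and macrophages. Car8 had a peak in 7 other tissues and none in cerebellum. The cerebellum list reached 72.7% in E14.5 brain against 54.5% in cerebellum itself. In olfactory bulb, 8 of 11 were occupied, including Sp8, a zinc-finger factor gene, and Eomes. Doc2g was not. The olfactory bulb list reached 72.7% in its own tissue and 81.8% in both E14.5 brain and small intestine.

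In thymus, 10 of 11 T-cell genes were occupied, including Cd8a, the T-cell co-receptor gene (chromosome 6, peak at 71323068 to 71324067), and Themis in thymus alone. The recombinase gene Rag1 had a Pol2 peak on the gene and none at its start. In spleen, 4 of 10 B-cell genes were occupied, including Ms4a1 (CD20) and Cd22 in spleen alone, and Cd19 was not. In bone marrow, 5 of 11 granulocyte genes were occupied, including Ngp and the calprotectin subunit gene S100a8 in bone marrow alone, and Camp was not. In bone marrow-derived macrophages, 6 of 10 were occupied, including Itgam (CD11b), also in thymus, and the mannose receptor gene Mrc1, also in liver. Cd68 was occupied in 5 other tissues and not in macrophages.

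The genes common to neurons were occupied more often in the neural tissues, with overlap between single tissues. Promoter peaks lay at 79.5% ± 23.9 (SD, n = 4) of the 11 neuronal genes in the 4 neural tissues and at 16.5% ± 16.7 (n = 11) in the others, a difference of 63.0 points (exact two-sided permutation p = 0.0015, adjusted p = 0.0088 over 6 such tests). E14.5 brain had peaks at 100% of them, olfactory bulb at 90.9%, cortex at 81.8% and cerebellum at 45.5%, while thymus also had 45.5% and small intestine 36.4%. The synaptic genes Snap25 and Syt1 were occupied in the first 3 of these and not in cerebellum. The difference was 60.6 points in the ELAND lists and 62.7 points in the Bowtie lists, where 2 neural lists each did not reach the adjusted threshold (adjusted exact permutation p = 0.11 and 0.16). In both batches the 2 neural lists had the 2 highest shares, so the unadjusted p was the smallest that so few lists allow. At equal list lengths the difference over all tissues was 31.8 points (31.8% against 0%, adjusted exact permutation p = 0.0022). The 10 pan-leukocyte genes had peaks at 57.5% ± 20.6 of cases in the 4 blood tissues and 38.2% ± 31.2 in the others (exact permutation p = 0.28, adjusted p = 0.34), a difference of 19.3 points that was 1.67 in the ELAND and 37.0 in the Bowtie lists. Among blood tissues, macrophages had peaks at 80.0% of them, thymus at 70.0%, and spleen and bone marrow at 40.0%. Among the others the share ran from 0% in kidney to 90.0% in lung, with 80.0% in small intestine, 70.0% in heart, 60% in testis and at most 30.0% in the rest. With every Pol2 list limited to its 5562 highest-signal peaks, the leukocyte difference was 43.0 points (47.5% against 4.55%, adjusted exact permutation p = 0.0022).

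Genes of the cell cycle were occupied at 100% in both E14.5 tissues and at 47.7% ± 33.9 (n = 13) in the adult ones (exact permutation p = 0.029, adjusted p = 0.086). Testis also reached 100%, and liver 0%. Without testis, the adjusted permutation p for the E14.5 tissues was 0.033. The difference of 52.3 points fell to 14.6 with the upper 50% of each list (adjusted permutation p = 0.83) and to 15.4 at equal list lengths (0.34). Among the Bowtie lists, which hold both E14.5 tissues, the difference was 20.0 points (adjusted exact permutation p = 0.60). Housekeeping promoters were occupied at 80.0% ± 26.3 over the 15 tissues and ribosomal protein promoters at 80.0% ± 31.6. They were 100% in liver, olfactory bulb, small intestine, testis, thymus and both E14.5 tissues. The lowest values were 16.7% and 25.0% in spleen and 41.7% and 8.33% in cerebellum. Immediate early genes averaged 72.0% ± 29.3 and erythroid genes 14.7% ± 13.0, with a highest erythroid value of 50.0% in bone marrow, where Hbb-b1 and Gypa were occupied. Markers of cell types shared between organs also had Pol2 peaks. Endothelial genes averaged 48.7% ± 27.7 and fibroblast genes 41.3% ± 30.7, and both reached 100% in heart. Adipose genes averaged 10.8% ± 9.29 and skeletal muscle genes 8.00% ± 13.7.

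The next question was which Pol2 regions were restricted to tissues of 1 system or age. After overlapping peaks of the 15 lists were joined, 64 regions were occupied in all 4 neural tissues and in none of the other 11. This was the 4th highest count among the 1365 choices of 4 tissues, whose highest was 82 (exact one-sided permutation p = 0.0029, adjusted p = 0.0071). Of the 64 regions, 41 lay within 1 kb of a transcription start, 8 were intronic, 4 exonic and 11 intergenic. The 8 with the highest mean signal percentile included the promoters of Rap1gap2 (chromosome 11, 74403045 to 74404161), Xkr4 (chromosome 1, 3660217 to 3662336), 6330407J23Rik, the orphan receptor genes Gpr123 and Gpr19, and Kcnt1, a sodium-activated potassium channel gene (chromosome 2, 25732761 to 25734757). The others were an intron of Anks1b (chromosome 10, 90291190 to 90292845) and a site 21842 bp from Smarcd3, which encodes a chromatin remodelling subunit. The set also held a promoter region of Gad1, which encodes an enzyme that makes the transmitter GABA and was picked out after its values were seen. Another start of Gad1 was occupied in small intestine. Without cerebellum, 254 regions were occupied in the other 3 neural tissues alone (adjusted permutation p = 0.013), and the count was 114 without olfactory bulb and 105 without E14.5 brain. Without cortex it was 93, rank 11 of 364, which did not pass (adjusted permutation p = 0.073). It was 22 with the upper 50% of each list and 8 with equal list lengths. Among the ELAND lists, 999 regions were found in cortex and cerebellum alone (adjusted exact permutation p = 0.12). Among the Bowtie lists, 516 were found in olfactory bulb and E14.5 brain alone (adjusted exact permutation p = 0.36).

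For the 4 blood tissues, 1 Pol2 region was shared by all and absent from the other lists, 16000 bp from Ptprc, the CD45 gene (chromosome 1, 140087882 to 140088962, intergenic). This count ranked 306th of 1365 (exact permutation p = 0.39, adjusted p = 0.47), but at equal list lengths it was 9 (adjusted permutation p = 0.0071). Within the batches 2 blood lists each shared 50 (ELAND) and 383 regions (Bowtie), neither past the threshold. The 2 E14.5 tissues shared 133 regions found in no adult list, 23rd among 105 pairs (exact permutation p = 0.22, adjusted p = 0.29), or 307 among the Bowtie lists alone. Of the 133, 50 lay at promoters, among them those of the patterning genes Hoxd11 (chromosome 2, 74519595 to 74521481) and Hoxd13 (74505596 to 74506806), Greb1l, Palld, which encodes an actin-associated protein, and Odz2. The other 3 of highest signal were intergenic, nearest to Hist2h2aa2, BC067074 and Ubash3b. No tissue had CTCF or Pol2 peak lists at both ages, so age and tissue cannot be separated.

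CTCF sites were shared between tissues more widely than Pol2 regions over all lists. On average 56.7% ± 10.9 of a tissue's CTCF peaks overlapped a CTCF peak of another tissue, as a mean over the other 14, against 45.7% ± 12.2 for Pol2. The difference was 11.0 points ± 13.4 and was positive in 12 of 15 tissues (exact two-sided sign-flip permutation p = 0.0066, adjusted p = 0.014). It was highest in cerebellum (40.2 points), and negative in thymus (-15.1), E14.5 brain (-1.20) and bone marrow (-0.45). The difference was 33.1 points in the 7 tissues with 2 ELAND lists (adjusted exact permutation p = 0.029) and -4.72 points in the 7 with 2 Bowtie lists (adjusted exact permutation p = 0.65), so it did not hold within the Bowtie batch. It fell to 6.25 points without cerebellum (adjusted permutation p = 0.13), to 8.40 without cortex (0.082) and to 7.76 with the upper 50% of each list (0.13). CTCF lists were longer, with a mean of 29058 peaks against 16874 for Pol2, and overlap with another list rises with its length. No alternative gave both targets the same list length, so the difference was not separated from list length.

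Joining overlapping peaks gave 101297 CTCF regions and 80860 Pol2 regions. Of the CTCF regions, 47069 (46.5%) were seen in 1 tissue, 23897 in 8 or more and 1206 in all 15. Of the Pol2 regions, 48450 (59.9%) were seen in 1 tissue, 10688 in 8 or more and 124 in all 15. Thymus alone gave 23568 of the CTCF regions seen in 1 tissue. For Pol2 the highest such counts were 8916 in heart and 7238 in testis. Promoters made up 96.0% of the Pol2 regions occupied in all 15 tissues and 12.3% of those in 1 tissue, while for CTCF these shares were 37.98% and 15.3%. Peaks in regions common to all tissues had the higher signal within their lists. For CTCF their median percentile was 75.3 ± 7.06, against 13.4 ± 6.73 for peaks in regions of 1 tissue, and for Pol2 it was 65.3 ± 9.21 against 19.3 ± 9.25. Both differences were positive in 15 of 15 tissues (exact sign-flip permutation p = 6.1e-05, the smallest possible, adjusted p = 0.00021). They were 48.4 and 34.9 points in the ELAND lists and 66.3 and 58.6 points in the Bowtie lists, the last with an adjusted exact permutation p of 0.053. At equal list lengths they were 53.2 points for CTCF and 26.4 points for Pol2. A region in all 15 lists had to pass the threshold of every list, while a peak near a threshold is easily missed in other lists. Such a difference can therefore arise from the thresholds alone.

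**Figure D2:**
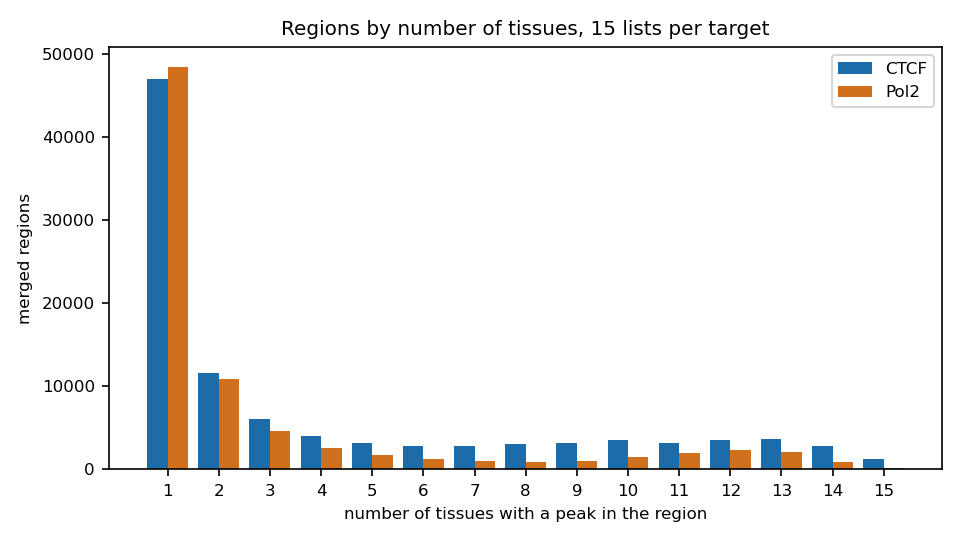
Number of merged regions (vertical axis) by the number of tissues with a peak in the region (horizontal axis), for CTCF and Pol2. Both distributions peak at 1 tissue (47069 and 48450 regions), and CTCF has 23897 regions in 8 or more tissues against 10688 for Pol2. The CTCF lists are longer on average, which is not corrected for here.

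CTCF lay at promoters less often than Pol2 in every tissue. Within 1 kb of a transcription start of a protein-coding gene lay 21.5% ± 7.80 of CTCF peaks and 61.9% ± 13.5 of Pol2 peaks. CTCF was lower in 15 of 15 tissues, by -40.5 points ± 14.8 on average (exact sign-flip permutation p = 6.1e-05, adjusted p = 0.00021). The widest gap was in bone marrow, with 19.3% for CTCF and 82.3% for Pol2, and the narrowest in small intestine, with 41.3% and 55.3%. The lowest Pol2 share was 38.5% in cerebellum. The difference was -43.3 points among tissues with 2 ELAND lists and -35.7 points among those with 2 Bowtie lists, where 7 tissues gave an adjusted exact permutation p of 0.053. It was -61.0 points at equal list lengths and -21.8 points with whole gene bodies in place of promoters. The CTCF share itself split by label, from 12.5 to 19.3% in the 7 ELAND lists and from 20.7 to 41.3% in the 8 Bowtie lists.

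**Figure D3:**
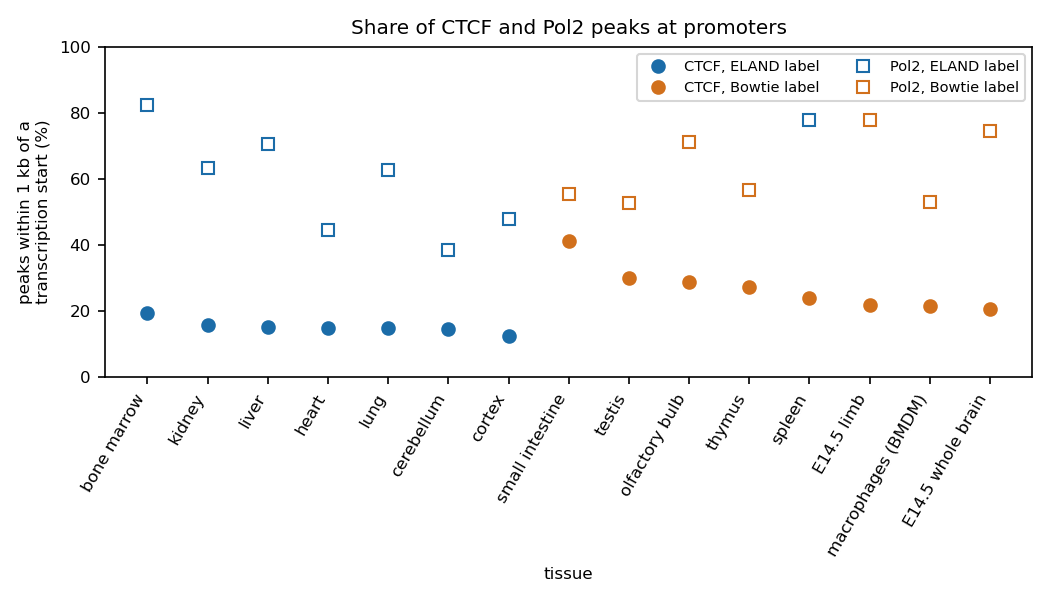
Percentage of CTCF peaks (filled circles) and Pol2 peaks (open squares) within 1 kb of a transcription start of a protein-coding gene, 1 point per tissue's list, coloured by the aligner named in the labels. Every CTCF point lies below the Pol2 point of its tissue, and the CTCF lists labelled ELAND (12.5 to 19.3%) lie below those labelled Bowtie (20.7 to 41.3%).

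On average, CTCF peaks also lay at a tissue's own marker genes more often than elsewhere, by fewer points than Pol2 peaks, a contrast that was not tested. They lay at 25.0% ± 17.9 of a tissue's own markers and at 16.3% ± 10.9 of them in the other tissues. After the mean of each tissue over all lists was subtracted, the difference was 8.73 points ± 12.0, positive in 11 of 15 tissues (one-sided permutation p = 0.00093, adjusted p = 0.0026). Without that subtraction it was negative in cortex (-11.4 points), small intestine (-8.93), bone marrow (-3.90), cerebellum (-2.60) and lung (-0.714). The own tissue ranked highest alone for heart only, where 5 of 12 cardiac genes had a CTCF peak. Of these, Tnni3, Myl2 and Ryr2 also had one in 12, 13 and 13 other tissues. The 5 of 12 liver genes with a CTCF peak in liver (41.7%) included Alb and Tat, but kidney had one at 66.7% of the liver list. Apoa1 and Apob, also among the 5, had one in 14 and 13 other tissues. The difference was 8.86 points in the ELAND lists and 7.04 points in the Bowtie lists (adjusted permutation p = 0.029 and 0.093), 3.97 points with the upper 50% of each list (0.035) and 13.6 points over whole gene bodies. CTCF peaks at neuronal genes were at 27.3% ± 10.5 in neural and 25.6% ± 14.0 in other tissues (exact permutation p = 0.84, adjusted p = 0.84). At leukocyte genes they were at 25.0% ± 20.8 in blood and 11.8% ± 4.05 in other tissues (exact permutation p = 0.071, adjusted p = 0.14), a difference of 13.2 points that was 21.5 without bone marrow (adjusted permutation p = 0.025) and 4.85 without thymus. At cell cycle genes they were at 50.0% ± 14.1 in E14.5 and 31.5% ± 14.6 in adult tissues (exact permutation p = 0.17, adjusted p = 0.26). Averaged over the 15 tissues, CTCF peaks lay at 63.3% of immediate early, 44.0% ± 16.4 of skeletal muscle, 38.3% ± 17.8 of ribosomal, 32.2% ± 16.3 of housekeeping and 29.3% ± 13.3 of fibroblast promoters. Endothelial, erythroid and adipose promoters had 24.0% ± 8.28, 24.0% ± 7.37 and 15.8% ± 12.9.

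Gene clusters at which CTCF is known to act differed in occupancy, given here as peaks per list with no test. All 4 Hox clusters held CTCF peaks in all 15 tissues, from 2 to 19 in Hoxa, 3 to 25 in Hoxb, 1 to 17 in Hoxc and 3 to 13 in Hoxd, with the highest counts in the longest list, thymus. Pol2 at Hoxd (chromosome 2, 74506367 to 74603200) was seen in 7 tissues, with 14 peaks in E14.5 limb, 8 in small intestine, 7 in kidney and testis, 6 in E14.5 brain, 4 in macrophages and 1 in olfactory bulb. The protocadherin gamma cluster held 5 to 21 CTCF peaks in all 15 tissues. The protocadherin alpha cluster (chromosome 18, 37089939 to 37347311) held 5.00 ± 2.94 in the 4 neural tissues and 1.91 ± 1.81 in the others, with 8 in cortex, 7 in E14.5 brain, 3 in cerebellum and 2 in olfactory bulb. Thymus had 6 and E14.5 limb 4. The beta cluster held 0 to 13, with the highest count in heart. The interval of the imprinted genes H19 and Igf2 held 1 to 8 CTCF peaks in all 15 tissues, and Pol2 there was listed in 5, macrophages, small intestine, E14.5 limb, thymus and E14.5 brain. The Xist and Tsix interval held CTCF peaks in 11 tissues. The interval of the recombinase genes Rag1 and Rag2 held CTCF peaks in thymus (2) and small intestine (1), and Pol2 peaks in 9 tissues, with 2 in thymus and 1 in each of the others. Within the beta-globin genes no list held a CTCF peak, and 1 Pol2 peak was listed, in bone marrow. That interval was only the 26.7 kb from Hbb-b1 to Hbb-y (chromosome 7, 110975048 to 111001754). Flanking sequence was not examined, so CTCF was not shown to be absent from the wider locus.

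**Figure D4:**
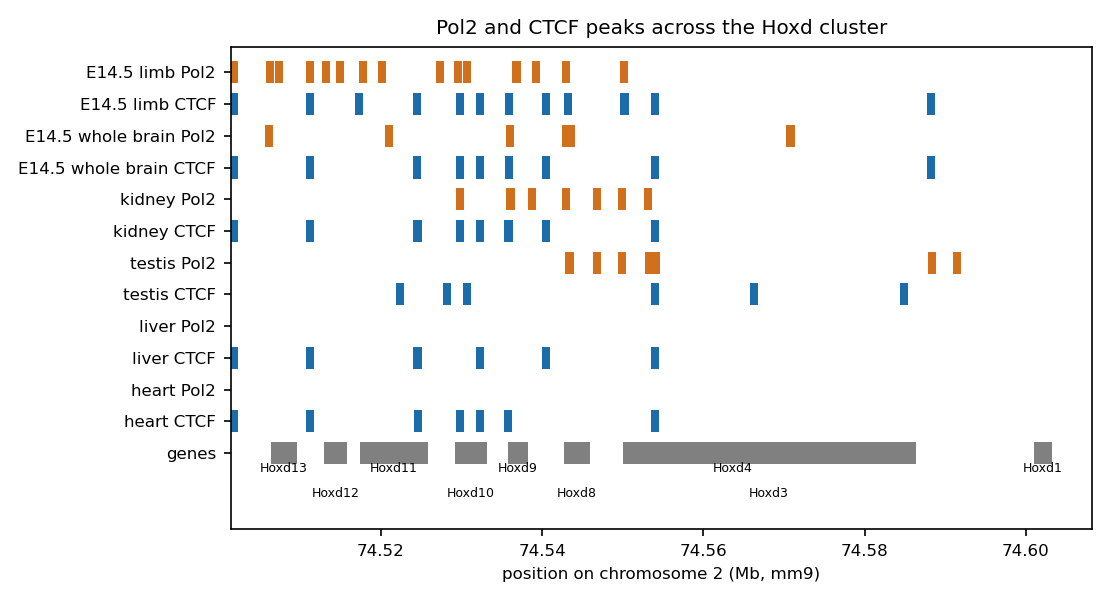
Positions of Pol2 and CTCF peaks across the Hoxd gene cluster on chromosome 2 (horizontal axis, Mb) in 6 of the tissues (rows), with the annotated genes in grey and Hoxd3 and Hoxd4 drawn overlapping as annotated. Between the ends of Hoxd13 and Hoxd1, E14.5 limb has 14 Pol2 peaks and liver and heart have 0, while CTCF peaks are present in all 6.

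CTCF regions restricted to 1 system were few. The 4 neural tissues shared 9 such regions (rank 86 of 1365, exact permutation p = 0.070, adjusted p = 0.12). They lay in introns of Igsf21 (chromosome 4, 139799468 to 139800641), Unc5a, a netrin receptor gene, Adcyap1r1, a neuropeptide receptor gene, Rbfox3, which encodes the neuronal nuclear marker NeuN, and Ttll11, at the promoter of Ksr2, and nearest to 1700010I14Rik and E2f8 among the 8 of highest signal. At equal list lengths the count was 14 (adjusted permutation p = 0.040), and without olfactory bulb it was 156 (0.057). The pairs of neural lists within a batch shared 448 (ELAND) and 98 regions (Bowtie). The 4 blood tissues shared 10 regions (rank 78 of 1365, exact permutation p = 0.062, adjusted p = 0.12), of which 6 were promoters. These were at Padi2 (chromosome 4, 140460935 to 140462475), Adcy7, Zc3h12d, Cpsf4, Prkag1 and Ptpn6, a phosphatase gene of blood cells, and other regions lay in E2f2 and Bcr. The 3 blood lists of the Bowtie batch shared 83 regions (adjusted exact permutation p = 0.54). The E14.5 tissues shared 458 regions absent from all adult lists (rank 9 of 105, exact permutation p = 0.086, adjusted p = 0.13), of which 104 were at promoters, 133 intronic, 48 exonic and 173 intergenic. Those of highest signal included the promoters of Hcn4, a pacemaker channel gene, Ccdc116 and Grm8, and sites in Adamts5, Pcdh11x and Sulf2 or near Rplp1 and Rtl1. The count was 149 with the upper 50% of each list (rank 9 of 105, adjusted permutation p = 0.13) and 36 at equal list lengths (rank 30 of 105, adjusted permutation p = 0.35). Without thymus it was 761 and ranked first (adjusted permutation p = 0.021). Among the Bowtie lists it was 4037 (adjusted exact permutation p = 0.093).

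Over all regions, neither neural nor blood tissues were shown to be closer to each other than to the rest. The mean Jaccard index, the share of 2 lists' combined regions found in both, was 0.456 among neural tissues and 0.406 between them and the others for CTCF (exact one-sided permutation p = 0.18, adjusted p = 0.26). For Pol2 it was 0.263 and 0.259 (exact permutation p = 0.47, adjusted p = 0.50). For blood it was 0.286 and 0.331 with CTCF (exact permutation p = 0.72, adjusted p = 0.72) and 0.272 and 0.264 with Pol2 (exact permutation p = 0.44, adjusted p = 0.49). Within the batches the 2 neural lists lay 0.0488 (ELAND) and -0.0502 (Bowtie) from the rest with CTCF, and 0.0103 and 0.165 with Pol2, none past the adjusted threshold. The blood lists lay -0.0319 from the rest with CTCF (Bowtie) and 0.109 (ELAND) and -0.0424 (Bowtie) with Pol2. The closest pairs were kidney and liver for CTCF (0.680) and E14.5 limb and E14.5 brain for Pol2 (0.628). Each of these pairs shared an aligner label, ELAND for the first and Bowtie for the second, so batch and tissue cannot be told apart in them. Across labels, the closest pairs were cortex and E14.5 brain for CTCF (0.644) and E14.5 limb and lung for Pol2 (0.433).

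CTCF and Pol2 of the same tissue occupied common sites slightly more often than those of different tissues. On average 16.3% ± 11.6 of CTCF peaks overlapped a Pol2 peak of the same tissue, from 4.18% in cerebellum to 45.0% in small intestine. After list effects were removed, same-tissue pairs exceeded others by 0.19 ± 0.14 on the log2 scale of observed over expected overlap, positive in 13 of 15 tissues. The one-sided permutation p was 1e-05, the smallest possible, with an adjusted p of 8.5e-05. Within the batches the excess was 0.19 (ELAND) and 0.14 (Bowtie), with adjusted exact permutation p of 0.0013 and 0.0084.

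In heart, p300 lay at sites of Pol2 more often than at sites of CTCF. Of the 39447 p300 peaks, 49.7% (exact binomial 95% interval 49.2 to 50.1%) overlapped a heart Pol2 peak and 25.1% (24.7 to 25.5%) a heart CTCF peak, and 35.3% overlapped neither. In the other direction, 67.6% of heart Pol2 peaks and 29.6% of heart CTCF peaks overlapped p300. By log2 observed over expected overlap, heart ranked first of the 15 Pol2 lists, at 4.49 against 4.41 for the next, spleen, a rank whose smallest exact p is 0.067. It ranked 10th of the 15 CTCF lists, and within the ELAND lists first of 8 for Pol2 and 4th of 7 for CTCF. Promoters made up 25.6% of p300 peaks, 41.7% of those with Pol2 alone and 7.13% of those with neither. A p300 peak lay at the start of 9 of 12 cardiac genes, the highest share of the 15 tissue lists, including Myl2, Actc1, Ryr2 and Pln, and not at Myh6. The next highest was the olfactory bulb list, with 2 of 11. All 10 endothelial, 10 immediate early, 12 housekeeping and 12 ribosomal genes had 1, as did 5 of 10 fibroblast, 4 of 10 cell cycle, 3 of 11 neuronal, 3 of 10 skeletal muscle, 2 of 8 adipose, 1 of 10 leukocyte and 1 of 10 erythroid genes. With each Pol2 list limited to 5562 peaks and each CTCF list to 14512, the shares were 12.7% for Pol2 and 17.6% for CTCF, and log2 observed over expected was 4.93 and 4.01. The intervals cover counting error only.

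The sex chromosomes did not settle the sex labels. The macrophage lists, labelled female, held no peak on the Y chromosome. Of the 12 male-labelled tissues, 10 had Y peaks with Pol2, up to 23 in liver, and 5 with CTCF, up to 4 in lung. Bone marrow, labelled male, held none with either target, so a lack of Y peaks did not mark the female label alone. The X chromosome held 0.887% of macrophage Pol2 peaks, against 2.43% ± 0.598 (n = 12) in male tissues, and 0.671% of macrophage CTCF peaks, against 1.79% ± 0.651. With 1 female list these are values without a test.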

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

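The tests of list length and of CTCF overlap for cerebellum were chosen after their results were seen. Of 6 tests of whether the difference between CTCF and Pol2 varies between classes of tissue, 1 had an unadjusted p below 0.05. The excess of CTCF over Pol2 sharing was -0.119 points ± 11.5 (SD, n = 4) in blood tissues and 15.1 points ± 12.1 (n = 11) in the others, a difference of -15.2 points (exact two-sided permutation p = 0.048, adjusted p = 0.27). It did not pass the adjustment. Thymus had the lowest CTCF sharing of the 15 tissues, 27.7%.

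Thymus held 23568 CTCF regions seen in no other tissue, 46.1% of its regions. The CTCF core sequence was found in 13.1% of the thymus-only peaks and in 13.9% of windows moved by 5 kb, an excess of -0.754 points. Thymus peaks shared with other tissues had an excess of 30.6 points. Own-only peaks also showed no excess in macrophages (13.1% against 13.3%), testis (11.1% against 12.6%), small intestine (10.3% against 11.7%) and olfactory bulb (13.3% against 15.9%). These lists and thymus all carry the Bowtie label. Every ELAND list showed an excess, such as 24.3% against 12.5% in bone marrow and 41.0% against 11.7% in liver. So did the other Bowtie lists, E14.5 limb (17.6% against 12.1%), spleen (21.1% against 16.3%) and E14.5 brain (30.2% against 10.0%). With every CTCF list limited to 14512 peaks, the share of own regions in thymus was 13.4%, 3rd after testis (23.1%) and bone marrow (14.9%) and above the median list (4.01%). Thymus-only CTCF peaks were enriched for thymus Pol2 above the Pol2 of the other tissues (rank 1 of 15), as was also the case in 14 of 15 tissues for their own CTCF-only peaks. A lower threshold or weaker enrichment, which may add peaks at open chromatin without direct CTCF binding, is 1 candidate. The lack of core sequence was not particular to thymus and was seen only under the Bowtie label. A difference of the batch and a difference of the tissue itself stay open.

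Cerebellum had the lowest share of Pol2 peaks at promoters, 38.5%, with peaks at 1 of 12 ribosomal protein genes. A short list was argued against, since the shorter spleen list had 78.0% and the bone marrow list 82.3%. Loss of GC-rich fragments stays open, since the GC values pointed both ways. Commonly occupied promoters that lacked a cerebellum peak had a GC content -2 points from those with 1, which speaks against such a loss. However, promoter peaks of the cerebellum list had the lowest GC content among the Pol2 lists, 56.9%, with heart next at 57.4%. CTCF signal in the Pol2 library stays open, since 12.4% of the cerebellum peaks away from promoters overlapped a cerebellum CTCF peak and 17.0% held the core sequence, both inside the ranges of the other tissues (9.48 to 43.1%, median 17.4%, and 8.90 to 24.4%, median 16.0%). Also open are a difference in preparation or threshold and a difference of the tissue, neither of which was tested. Of all cerebellum peaks, 36.6% lay on gene bodies away from promoters, against 7.89 to 31.7% elsewhere. Since this share is of all peaks in a list, a low promoter share raises it by itself, and it cannot decide between these.

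CTCF promoter shares split by aligner label, with a mean of 26.9% ± 6.78 in 8 Bowtie lists and 15.3% ± 2.04 in 7 ELAND lists (exact two-sided permutation p = 0.00047). List length was argued against, since at equal lengths the ranges stayed 0.662 points apart, with a mean difference of 13.8 points (exact permutation p = 0.0017). Promoter CTCF peaks held the core sequence less often in the Bowtie lists, a difference of -15.3 points (exact permutation p = 0.00062), and their peaks away from promoters were richer in GC by 2.79 points (exact permutation p = 0.0012), but both pairs of ranges overlapped. Away from promoters the core sequence was also less frequent in the Bowtie lists, at 59.0% ± 12.6 against 67.7% ± 2.18. That difference was -8.74 points (exact two-sided permutation p = 0.080). The lower share was thus not shown to be particular to promoters. More indirect or GC-rich promoter signal in the Bowtie batch stays open. Batch and tissue cannot be told apart, because no tissue has CTCF lists under both labels, and the Pol2 promoter shares of the same batches differed by 4.51 points.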

How the results depend on the processing

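The alternatives for clustering and for the neuronal, leukocyte and cell cycle lists were added after seeing the data. The own-tissue excess of Pol2 (24 alternatives), the same-tissue overlap of CTCF and Pol2 (22), and the signal of shared CTCF regions (23) kept their direction and their side of the threshold under every alternative run. Over all tested results, counts of regions included, the adjusted p ended a call 15 times and gained a call 6 times, and 21 alternatives turned a direction. The cause was not tested, except that fewer lists or peaks by construction change counts of restricted regions and overlap shares. With 7 tissues in a batch the smallest sign-flip p is 0.015625, which limits the calls within a batch. Class tests within a batch have few choices of lists, which limits their calls likewise.

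The excess of CTCF over Pol2 sharing was 7.76 points with the upper 50% of each list and -4.72 in the Bowtie lists, and ran from 6.25 to 13.8 with single tissues left out. Also in the Bowtie lists, the promoter difference was -35.7 points, the CTCF own-tissue excess 7.04 points and the signal difference of shared Pol2 regions 58.6 points, all short of the adjusted threshold. Clustering turned to 0.118 points with the upper 50% and 2.58 at equal lengths, and was -1.79 in the Bowtie lists.

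The neural similarity difference for Pol2 was -0.00272 with an overlap of at least 500 bp, -0.0435 with the upper 50%, -0.0695 at equal lengths and -0.0336 with the overlap coefficient, and ran from -0.0341 to 0.0788 with single tissues left out. For CTCF it was -0.0502 in the Bowtie lists. The blood similarity difference for Pol2 was -0.0109 with the upper 50% and -0.0424 in the Bowtie lists, and ran from -0.0157 to 0.0315 with single tissues left out. None of these differences passed the test under the alternatives named.

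Neural-only Pol2 regions numbered 22 with the upper 50%, 8 at equal lengths, 999 in the ELAND lists and 516 in the Bowtie lists, and 64 to 254 with single tissues left out. Blood-only Pol2 regions numbered 2 with an overlap of at least 500 bp and 2 with the upper 50%, 9 at equal lengths, 50 in the ELAND lists and 383 in the Bowtie lists, and 1 to 10 with single tissues left out. E14.5-only Pol2 regions numbered 41 with the upper 50%, 81 at equal lengths and 307 in the Bowtie lists. Neural-only CTCF regions numbered 14 at equal lengths, 448 in the ELAND lists and 98 in the Bowtie lists, and 9 to 156 with single tissues left out. Blood-only CTCF regions numbered 83 in the Bowtie lists and 10 to 40 with single tissues left out. E14.5-only CTCF regions numbered 149 with the upper 50%, 36 at equal lengths and 4037 in the Bowtie lists, and 463 to 761 with single adult tissues left out.

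The share of heart p300 peaks on Pol2 was 45.8% with an overlap of at least 500 bp, 32.3% with the upper 50% and 12.7% at equal lengths, and on CTCF 22.4%, 16.2% and 17.6%. The CTCF difference at cell cycle genes was -3.08 points with the upper 50% and -4.62 at equal lengths, and at neuronal genes it ran from -1.38 (without olfactory bulb, or without E14.5 brain) to 4.68 with single tissues left out. Neural-only Pol2 regions lost their call in the ELAND lists, the Bowtie lists and without cortex (93 regions). Pol2 at neuronal genes lost its call in the ELAND (60.6 points) and Bowtie lists (62.7 points). There the 2 neural lists of each batch had the highest shares, so the unadjusted p could not be smaller. Blood similarity and blood-only regions for CTCF could not be computed in the ELAND lists, which hold 1 blood tissue, nor E14.5-only regions in the ELAND lists or without either E14.5 tissue. By replicate number, no paired analysis was possible because each target had 1 list per tissue, while CTCF and Pol2 were paired by tissue. Read depth behind the peaks is unknown, so its effect on list length could not be measured.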

Other observations

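The tests of the core sequence and of clustering were chosen after the data were seen. The CTCF core sequence was less frequent in CTCF peaks seen in 1 tissue than in shared ones. It was present in 64.7% ± 1.02 (SD, n = 15) of CTCF peaks in regions occupied in all 15 tissues, 61.3% ± 7.01 of those in 2 to 14 tissues and 24.9% ± 11.6 of those in 1 tissue, against 15.04% ± 0.36, 13.4% ± 0.972 and 11.8% ± 2.52 of windows moved by 5 kb. The difference between all tissues and 1 tissue was 39.8 points ± 11.0 and was positive in 15 of 15 tissues (exact two-sided sign-flip permutation p = 6.1e-05, the smallest possible). Peaks in 1 tissue also had the lower signal within their lists, with a median percentile of 13.4 against 75.3 for those in all tissues. No comparison matched for signal was run, so sharing was not separated from peak strength. Peaks in 1 tissue held the sequence more often than moved windows in every ELAND list. They did not in macrophages, testis, thymus, small intestine and olfactory bulb, all Bowtie lists. CTCF peaks away from promoters held the sequence in 63.1% ± 10.1 of cases and promoter peaks in 41.5% ± 9.84. Over all CTCF peaks the share ran from 30.8% in thymus to 68.1% in liver.

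Pol2 peaks held the CTCF core sequence in 14.96% ± 2.12 of cases, against 13.2% ± 0.785 of moved windows. In the heart p300 list it was present in 23.7% of peaks, against 12.3% of moved windows. The 5 p300 peaks of highest score lay in an exon of Cmtm5 (chromosome 14, 55557313 to 55558312), in an intron of Fhl2, which encodes a LIM-domain protein of the heart, at the promoter of Cd36, the fatty acid translocase gene (chromosome 5, 17341339 to 17342338), and in intergenic sequence nearest to Gm9956 and A1bg.

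CTCF peaks were less clustered than Pol2 peaks over the full lists. Another peak of the list started within 2 kb for 11.6% ± 3.52 of CTCF peaks and 17.8% ± 6.25 of Pol2 peaks, a difference of -6.15 points ± 8.39, negative in 11 of 15 tissues (exact sign-flip permutation p = 0.015). The measure replaced peak width after the data were seen, and its direction turned under other list lengths.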
